A study of Bos taurus with 4 samples.

How the data were processed

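RNA of bovine blastocysts was measured on 4 arrays with 2 channels each. Per the labels, every array carried embryos sired with semen taken at 12 months of age in one channel and embryos sired with semen taken at 16 months in the other. The 12-month RNA was in Cy5 on arrays 1 and 2 and in Cy3 on arrays 3 and 4, so the dye orientation was balanced. The labels describe the arrays as biological replicates and name 4 bulls, each sampled at both ages. They do not tie a bull to an array, and the number of embryos behind each RNA is not given in the sources used here.

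Per the labels' protocols, total RNA was amplified with a linear amplification kit and the amplified RNA was labelled chemically with Cy3 or Cy5. Amplification can change the relative abundance of transcripts, and it does so in the RNA of both ages. The deposited scanner files give, per the file headers, the intensity of each spot and of its surroundings as the median and the mean over pixels, at 532 nm for Cy3 and 635 nm for Cy5, with no background subtracted. The scanner and its software are not given in the sources used here. Each array held 45220 spots, of which 1426 were control or unlabelled spots and 43794 were probes, 1 spot per probe. The 14 summary lines at the foot of each file were left out. The submitters' processing notes name limma, with no version and no model.

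The authors' deposited value table holds 1 value per probe and array on a log2 scale. Set against the scanner files, each column followed the loess-normalised log2 ratio of Cy5 over Cy3 of its own array, with r across probes from 0.988 to 0.994 and slopes from 0.930 to 1.05. The highest r with another array was 0.330. The direction is therefore Cy5 over Cy3 on every array, not reversed where the dyes were swapped. Column medians were -0.016, -0.0019, -0.012 and -0.0063 for arrays 1 to 4. The exact background step behind that table stays unknown, and it was used only as an alternative.

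From the median intensities, background was corrected with normexp and an offset of 50, and log2 ratios were normalised by loess within each array with control spots at weight 0. Spots that the scanner software marked as ignored were left out. These were 13, 10, 64 and 818 spots on arrays 1 to 4. A probe was tested when its background-subtracted signal exceeded the 95th percentile of the 153 negative control spots of the same array and channel in at least 4 of the 8 channel signals, which kept 30986 probes. The share of probes above that level was 69.5% to 72.3% in Cy5 and 62.7% to 66.6% in Cy3. The number of arrays limits the precision, and the median half-width of the 95% confidence interval of a probe was 0.23 on the log2 scale.

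Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 coefficient for age and 1 for the dye, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Values are log2 ratios of 12 over 16 months, so a positive value is higher in embryos of the 12-month semen. A value is given as the mean over arrays ± SD over arrays. The SD includes the dye effect, while the test removes it. Each array contrasts both ages within itself, so array-wide differences cancel in the ratio. All 4 arrays lay on 1 slide. No batch of fertilisation, amplification or labelling is known here, so one that splits the arrays or the channels cannot be excluded. Each bull was sampled at both ages, so age goes with the time of collection, which the ratio does not cancel.

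Gene symbols came from the platform annotation. It names 1 symbol for 21790 probes, several for 0 and none for 22004. Of the named probes 20068 had a current symbol in the RefSeq gene table of assembly ARS-UCD2.0, 1644 were updated through a synonym and 78 found no match and kept their name. Y-linked list symbols were not updated, because a synonym can name an autosomal copy. No genome was used, so probe positions and matches to related genes were not examined. For gene lists, each gene was represented by its brightest probe measured on all arrays, which gave 11961 genes. Of 27 lists fixed before the data were examined, 25 had at least 3 genes. The list of mitochondrially encoded transcripts had 0 genes with a tested named probe, and the interferon tau list had 2. Lists were tested with limma's camera at a correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera with a correlation estimated per list and fry stand beside it, and counts adjusted over the list alone are given.

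Named genes followed a rule fixed before the data were examined. It takes the 12 higher and 12 lower genes with the smallest p among those with the same sign on all 4 arrays, skipping symbols that are only locus or clone names (1 skipped in each direction). It adds, per list, the members past the threshold over all probes or over the list alone, up to 4, and otherwise the 2 members with the smallest p. Y-linked and interferon tau genes were all given.

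The procedure was tested on simulated data with 200 changed probes among 30388 and 20 repeats. At the adjusted threshold it recovered 0% of 1.5-fold changes, 86.8% of 2-fold changes and 99.4% of 4-fold changes. In simulated lists of 40 independent genes, camera at 0.01 found a shift of 0.15 in 20 of 20 repeats, at an unadjusted p under 0.05. At that unadjusted level it also called 12 of 20 lists that had no age effect but shared a random component within each array. That component had an SD of 0.2, and camera with an estimated correlation called 1 of 20. How often camera with an estimated correlation finds a real shift was not simulated.

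Alternatives covered the dye term, the background correction, the normalisation within and between arrays, the filter on dim probes, array weights, the eBayes prior, the authors' deposited ratios, each array left out in turn, the mean over a gene's probes and the list test. Mean pixel brightness and the removal of spots with a local Cy3 background above 300 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.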

Results

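The study asked whether the age of a bull around puberty is visible in the transcriptome of the embryos he sires. Blastocysts, embryos with a fluid-filled cavity, an outer trophectoderm and an inner cell mass, were produced in vitro with semen collected at 12 or at 16 months of age. RNA of embryos from the 2 ages was hybridised together on each of 4 arrays of bovine embryo probes, with the dyes exchanged on 2 of them. Of 43794 probes, 30986 were bright enough to be tested, and 16540 of these carried a gene symbol.

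No single transcript passed the test between the ages, and the differences averaged over arrays were small. The named genes were those with the smallest p among genes with 1 direction on all 4 arrays, and other such genes may have larger values. Of the named genes higher with 12-month semen, SIL1, a cochaperone of the endoplasmic reticulum, was largest at 0.57 ± 0.33 on the log2 scale (SD, n = 4). MYC, a transcription factor of cell growth, followed at 0.56 ± 0.42. In the other direction stood ID3, an inhibitor of helix-loop-helix transcription factors, at -0.78 ± 0.43 and BTG4, an adaptor in the clearance of maternal mRNA, at -0.66 ± 0.62. In limma, 0 probes passed an adjusted p of 0.05 or of 0.1, and the smallest adjusted p was 0.821. At an unadjusted p under 0.05 stood 1799 probes, 933 higher and 866 lower with 12-month semen, where 1549.3 would be expected by chance. This even split depended on the normalisation, with 199 higher and 8902 lower after median centring in place of loess. Median centring, unlike loess, leaves any brightness-dependent bias in place. The median absolute log2 ratio was 0.083, and 99.9% of probes lay within 1.5-fold. These are means over arrays of differing direction, and the ratios of a single array had an SD across probes of 0.24 to 0.31. Only 31 probes exceeded 1.5-fold at an unadjusted p under 0.05. All 4 arrays had the same sign for 3160 probes, or 10.4% of those measured on every array, against 12.5% if signs were independent. A probe's dye effect points apart in the 2 dye orientations and lowers this share, so 12.5% is not the chance level of this design. Leaving out array 3 brought 26 probes past the threshold and leaving out array 4 brought 17, while leaving out array 1 or array 2 brought 0. Each of these fits has a lone array in 1 dye orientation, which is assumed to vary like the others, so the spread came from arrays 1 and 2 alone in the first 2 and from arrays 3 and 4 alone in the last 2.

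The arrays agreed poorly in the direction of the age difference. Across probes, the log2 ratios of 12 over 16 months correlated at 0.33 between arrays 1 and 2, which share a dye orientation, and at -0.15 between arrays 3 and 4, which share the opposite one. Array 4 correlated at -0.24 with array 1 and at -0.11 with array 2, and array 3 at 0.0075 with array 1 and -0.054 with array 2. These correlations are across genes, which are not independent replicates.

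The 12 named genes on the higher side did not pass the test after adjustment and are given as values. MID1IP1, an activator of fatty acid synthesis, stood at 0.53 ± 0.37, and CIDEB, a lipid droplet protein, at 0.47 ± 0.49 with a second probe at -0.13. VAV3 stood at 0.50 ± 0.18, ZAP70, a kinase of the T cell receptor, at 0.47 ± 0.26, and PROCR, the protein C receptor, at 0.45 ± 0.17. DTNBP1 (dysbindin) stood at 0.50 ± 0.30, ATXN1L at 0.44 ± 0.13, LGALS9, a galectin, at 0.41 ± 0.39, CASQ1, a calcium-binding protein, at 0.39 ± 0.44 and SLC66A3 at 0.39 ± 0.37 (all n = 4). A second SIL1 probe stood at -0.074, and 1 of the 3 further LGALS9 probes was also below 0, at -0.0086. After median centring in place of loess, which put the median of all probes at -0.14, the 12 genes ranged from -0.0098 for ZAP70 to 0.44 for SIL1, with VAV3 at 0.12.

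The 12 named genes on the lower side were likewise short of the adjusted threshold. The glucose transporter SLC2A1 was 1 of the most even, at -0.42 ± 0.070 with arrays between -0.35 and -0.52, although a dimmer second probe stood at 0.020. GLRX, a glutaredoxin, stood at -0.55 ± 0.23, DPCD at -0.48 ± 0.24, MOV10, an RNA helicase, at -0.46 ± 0.15, and RPS27, a ribosomal protein, at -0.45 ± 0.19. GALNT11, an enzyme of O-linked glycosylation, stood at -0.43 ± 0.13, and CSNK2B, the regulatory subunit of casein kinase 2, at -0.43 ± 0.14. AGPAT5, an acyltransferase of phospholipid synthesis, stood at -0.42 ± 0.070, TBC1D24 at -0.40 ± 0.11 and DDX51, an RNA helicase, at -0.39 ± 0.12 (all n = 4). ID3 rested on 1 of 4 probes, with the others at 0.011, -0.061 and 0.066. After median centring the 12 genes ranged from -0.99 for GLRX to -0.56 for TBC1D24, with SLC2A1 at -0.87. BTG4 was above background on 4 arrays in the 16-month RNA and on 2 in the 12-month RNA.

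**Figure D1:**
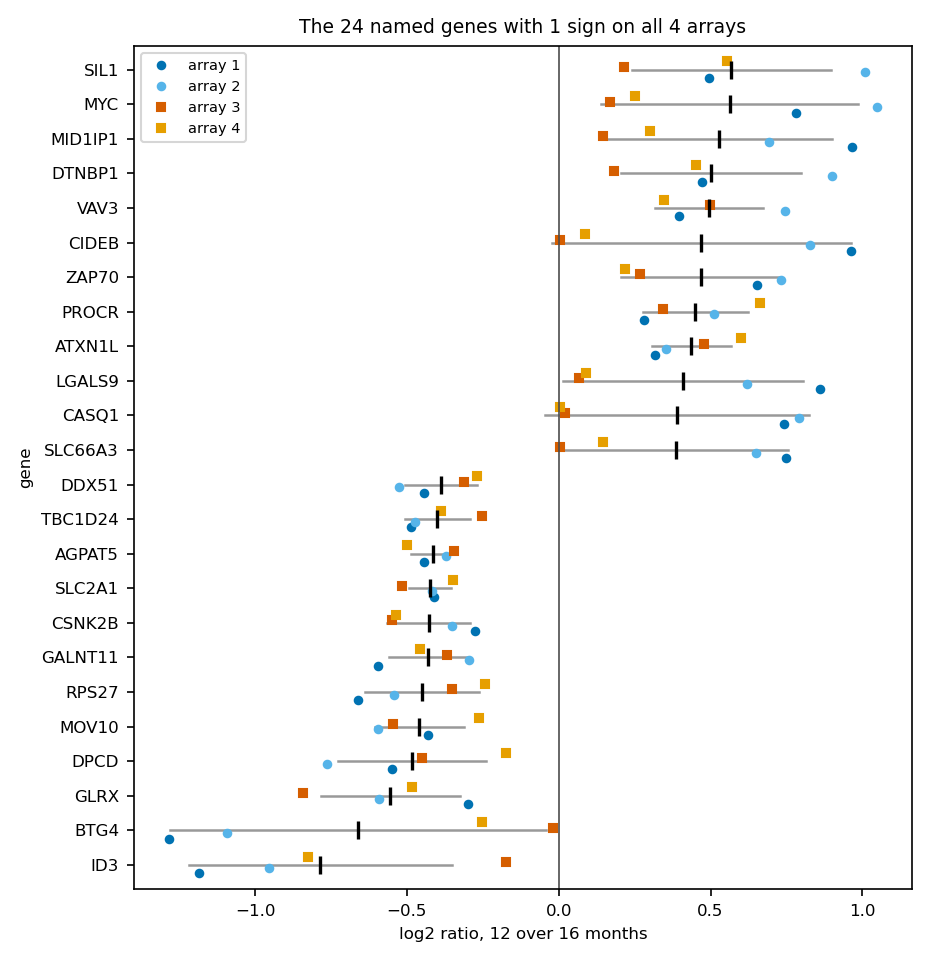
Log2 ratio of 12 over 16 months (horizontal axis) of the 24 named genes (vertical axis), with circles for arrays 1 and 2, squares for arrays 3 and 4, a black tick at the mean and a grey line of 1 SD to each side (n = 4). All points of a gene lie on 1 side of 0, from -0.78 on average for ID3 to 0.57 for SIL1, and none of the genes passed the adjusted threshold.

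Of 25 gene lists, those of oxidative phosphorylation, ribosomal proteins and the cell cycle passed the test on the lower side with 12-month semen and an X-linked list on the higher side, at the preset correlation of 0.01. All 4 calls were lost with an estimated correlation (adjusted p = 0.865 for each in camera). That version called 0 lists under each of the 7 sign patterns of the arrays. Its power to find a real shift was not simulated, so the loss cannot decide. At the preset correlation, turning arrays 2 and 4 round called 8 lists, and turning arrays 2 and 3 round called 1. As many calls as the real 4 can thus arise under labels other than age. Of 75 nuclear genes of oxidative phosphorylation, 65 were lower and 10 higher, with a median log2 ratio of -0.15. SDHA, a subunit of succinate dehydrogenase, stood at -0.37 ± 0.28 and ATP5PD, a subunit of ATP synthase, at -0.38 ± 0.34 (n = 4). Of 63 cytosolic ribosomal proteins, 52 were lower and 11 higher, with a median of -0.12. RPS27 and RPS3A had the smallest p of this list, RPS3A at -0.35 ± 0.049 with all 4 arrays below 0. Of 37 cell cycle genes, 30 were lower and 7 higher, with a median of -0.11. RRM2, a subunit of ribonucleotide reductase, stood at -0.32 ± 0.45 and MCM3, a part of the replicative helicase, at -0.32 ± 0.20. Of 25 X-linked genes often higher in female embryos, 21 were higher and 4 lower, with a median of 0.11. This median was below 0 after median centring in place of loess (-0.26 against -0.21 for all genes) and without array 4 (-0.013, adjusted p = 0.857). After median centring the medians of oxidative phosphorylation, ribosomal proteins and the cell cycle were -0.61, -0.58 and -0.53. Relative to all genes these were -0.39, -0.37 and -0.32. Median centring leaves brightness-dependent bias in place, so these larger shifts of bright lists need not reflect age. No member of these 4 lists passed the threshold over all probes or adjusted over the list alone.

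With limma's camera at a correlation of 0.01, adjusted p was 2.95e-09 for oxidative phosphorylation, 4.79e-07 for ribosomal proteins, 1.18e-05 for the cell cycle and 0.00214 for the X-linked list. With fry, which tests a list against no change and not against other genes, adjusted p was 0.824 for each. The array medians varied widely. Oxidative phosphorylation stood at -0.37, -0.17, -0.17 and 0.11 on arrays 1 to 4, ribosomal proteins at -0.14, 0.069, -0.40 and -0.042, the cell cycle at -0.28, -0.098, -0.0093 and 0.018, and the X-linked list at 0.21, 0.22, -0.21 and 0.20. Without array 3 the ribosomal median was -0.037 (adjusted p = 0.107) and that of oxidative phosphorylation -0.069. Without array 1 the adjusted p of the X-linked list was 0.0542.

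**Figure D2:**
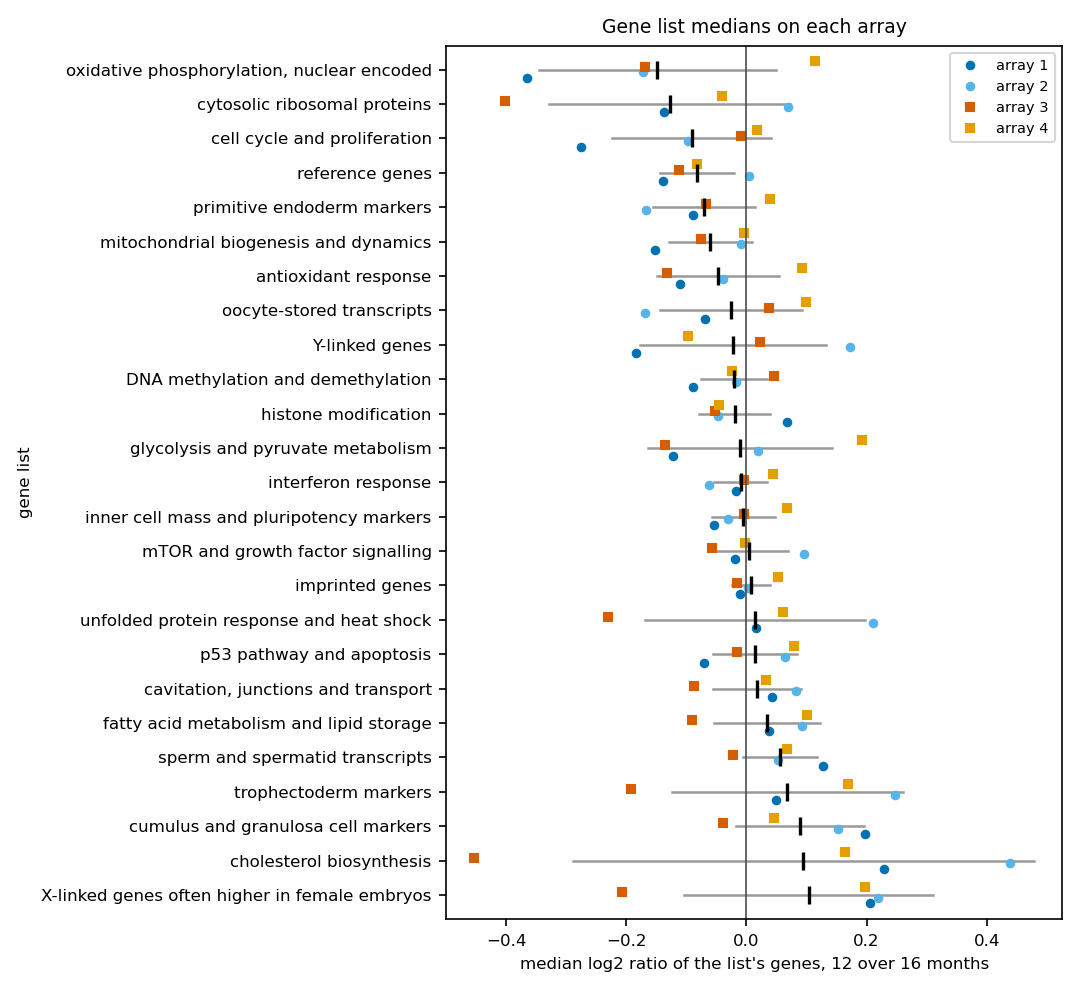
Median log2 ratio of 12 over 16 months (horizontal axis) over the genes of each of 25 lists (vertical axis), with circles for arrays 1 and 2, squares for arrays 3 and 4, a black tick at the mean over arrays and a grey line of 1 SD to each side (n = 4). Oxidative phosphorylation lies lowest, with arrays from -0.37 to 0.11, and cholesterol biosynthesis spreads most, from -0.45 to 0.44; the X-linked list is above 0 on arrays 1, 2 and 4, which does not hold after median centring.

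The sex-linked genes gave an uneven picture. XIST, the noncoding RNA that coats the inactive X chromosome, stood at 0.39 ± 0.22 (n = 4), higher with 12-month semen on 4 of 4 arrays. BEX2, also X-linked, stood at 0.32 ± 0.29 and was higher on 3 of 4. Adjusted over the list alone, adjusted p was 0.239 for XIST and 0.366 for BEX2. The Y-linked genes lay close to background, with EIF1AY at -0.11 ± 0.13, DDX3Y at -0.046 ± 0.20 and SRY at -0.017 ± 0.23. Their list had a median of -0.046 and an adjusted p of 0.693 in camera. Of the 8 channel signals, DDX3Y was above background in 8, EIF1AY in 7 and SRY in 5. Of the 25 X-linked genes 6 also belong to another list, XIST among them.

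Markers of the blastocyst lineages did not pass the main test. For trophectoderm, the outer layer that forms the placenta, 15 of 21 markers were higher and 6 lower with 12-month semen, with a median of 0.035 (adjusted p = 0.256 in camera). The list passed with mean in place of median pixel brightness (median 0.054, adjusted p = 0.0447) and without array 3 (0.11, adjusted p = 1.43e-05), against an adjusted p of 0.865 for the main values with an estimated correlation. CYP11A1, the first enzyme of steroid synthesis, stood at 0.62 ± 0.72 and PAG12, a pregnancy-associated glycoprotein, at 0.56 ± 0.50, both higher on arrays 1, 2 and 4 and lower on array 3. Interferon tau, the pregnancy recognition signal of ruminant trophectoderm, stood at 0.42 ± 1.02 for IFNT, from -0.88 on array 3 to 1.42 on array 2, and at 0.31 ± 0.41 for IFN-tau-c1. Of 16 inner cell mass and pluripotency markers 9 were higher and 7 lower, with a median of 0.063 (adjusted p = 0.693), IL6R at 0.29 ± 0.30 and SOX2 at 0.22 ± 0.32. Of 20 primitive endoderm markers 7 were higher and 13 lower, with a median of -0.069 (adjusted p = 0.256). Its members with the smallest p, LAMA1 and COL4A1, stood at -0.64 ± 0.58 and -0.35 ± 0.15 (n = 4 throughout).

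Transcripts that the embryo could carry over from the gametes or from cells around the oocyte gave 1 gene past a threshold. BTG4 was the only 1 of 19 oocyte-stored transcripts past the threshold adjusted over the list alone (adjusted p = 0.00572 in limma, against 0.821 over all probes). It was lower with 12-month semen on 4 of 4 arrays, at -1.28, -1.09, -0.020 and -0.25, so arrays 1 and 2 carried the value. In the 12-month RNA it was above background on 2 arrays. Adjustment over a list alone does not count the 25 lists, over which 2 genes passed in all, BTG4 and SDHA. The oocyte-stored list itself had 7 genes higher and 12 lower, a median of -0.027 and an adjusted p of 0.390 in camera. Of 14 cumulus and granulosa cell markers 10 were higher and 4 lower, with a median of 0.065 (adjusted p = 0.306). HSD3B1, an enzyme of progesterone synthesis, stood at 0.73 ± 0.70 and STAR, a cholesterol carrier, at -0.29 ± 0.18, with further STAR probes at -0.18 and 0.062. Of 13 sperm and spermatid transcripts 8 were higher and 5 lower, with a median of 0.065 (adjusted p = 0.438), the protein TNP1 of sperm chromatin at 0.23 ± 0.27 and DKKL1 at 0.25 ± 0.22 (n = 4). The sperm list, of dim genes (median log2 intensity 7.63), passed after median centring, which leaves brightness-dependent bias in place. Its median was then 0.0049, or 0.22 relative to all genes (adjusted p = 0.00808 in camera). The cumulus median without array 3 was 0.086. With all 4 arrays and an estimated correlation, adjusted p in camera was 0.865 for each of these lists.

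**Figure D3:**
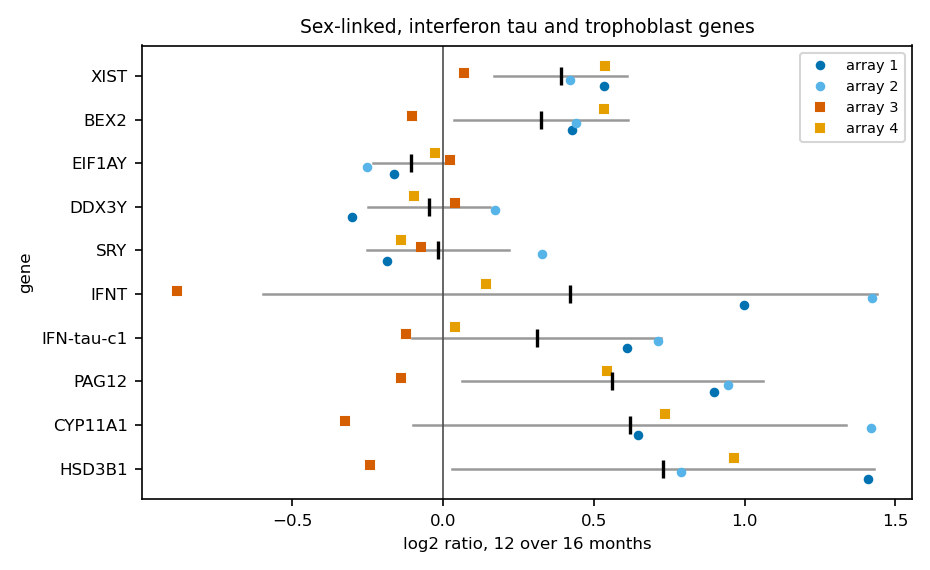
Log2 ratio of 12 over 16 months (horizontal axis) of sex-linked, interferon tau and trophoblast or steroid genes (vertical axis), with circles for arrays 1 and 2, squares for arrays 3 and 4, a black tick at the mean and a grey line of 1 SD to each side (n = 4). XIST is above 0 on all 4 arrays, whereas BEX2, IFNT, IFN-tau-c1, PAG12, CYP11A1 and HSD3B1 are below 0 on array 3 alone; none passed the adjusted threshold.

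Metabolic and stress lists other than oxidative phosphorylation did not pass the main test, but 5 of them passed in 1 alternative each. After median centring in place of loess these were glycolysis and mitochondrial biogenesis on the lower side (adjusted p = 0.0260 for each), without array 4 the antioxidant list on the lower side (0.0404), and without array 3 cholesterol biosynthesis (7.62e-05) and the unfolded protein list (0.0406) on the higher side. With all 4 arrays and an estimated correlation, adjusted p was 0.865 for cholesterol biosynthesis and mitochondrial biogenesis and 0.879 for the other 3. Cholesterol biosynthesis had a median of 0.073 with 12 of 19 genes higher (adjusted p = 0.238), and HSD17B7 and PMVK stood at 0.23 ± 0.43 and 0.25 ± 0.32, with a second PMVK probe at -0.098. Fatty acid metabolism and lipid storage had a median of 0.013 (adjusted p = 0.693), with HADHB at -0.23 ± 0.15 and CD36 at -0.17 ± 0.40, with further CD36 probes at -0.11 and 0.00016. Glycolysis had a median of 0.010, a mean of -0.00036 and a test direction below 0 (adjusted p = 0.799), and its median after median centring was -0.42. Its members SLC2A1 and TPI1, an enzyme of glycolysis, pointed apart, TPI1 at 0.55 ± 0.62. Mitochondrial biogenesis and dynamics had a median of -0.067 (adjusted p = 0.372), with the rRNA methyltransferase TFB1M at -0.35 ± 0.33 and ESRRA at 0.23 ± 0.10. The antioxidant list had a median of -0.034 (adjusted p = 0.693), with the metallothionein MT1E at -0.35 ± 0.43 and PRDX5 at -0.26 ± 0.18, each with a second probe above 0. The unfolded protein and heat shock list had a median of 0.053 (adjusted p = 0.693), with HSPA1A, a heat shock protein, at 0.63 ± 0.87 and DNAJC3 at -0.24 ± 0.21. The p53 and apoptosis list had a median of 0.018 (adjusted p = 0.693), with BID at -0.35 ± 0.26 and APAF1 at 0.28 ± 0.22 (n = 4 for each gene).

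Epigenetic, signalling and reference lists did not pass the main test. DNA methylation and demethylation had a median of -0.0086 (adjusted p = 0.693 in camera). Its members SHMT2 and GNMT, enzymes of methyl group metabolism, stood at -0.22 ± 0.27 and -0.24 ± 0.28, with further SHMT2 probes at -0.072, 0.00058 and 0.030. Histone modification had a median of -0.0028 (adjusted p = 0.80), with the methyltransferases SETD7 at 0.23 ± 0.25 and EHMT1 at -0.17 ± 0.087. Imprinted genes had a median of -0.022 (adjusted p = 0.693), with GNAS at -0.35 ± 0.33 and its further probes at -0.068 and 0.025. The mTOR and growth factor list had a median of 0.0040 (adjusted p = 0.80), with PIK3CB at 0.21 ± 0.28 and IGF1R at 0.21 ± 0.21. The junction and transport list of cavitation had a median of -0.0014 (adjusted p = 0.80), with JUP at -0.31 ± 0.11 and CLDN1 at 0.29 ± 0.047, components of cell junctions that each kept 1 sign on all arrays. The interferon response list had a median of -0.036 (adjusted p = 0.693), with IFI27 at -0.16 ± 0.12 and MX2 at 0.28 ± 0.27, above background on 4 arrays in the 12-month RNA and on 2 in the 16-month RNA. The reference gene list, of bright genes (median log2 intensity 13.5), had a median of -0.078 (adjusted p = 0.331 in camera). After median centring, which leaves brightness-dependent bias in place, this list stood at -0.52, or -0.31 relative to all genes. Adjusted p was then 0.00140 in camera, against 0.865 for the main values of the list with an estimated correlation. SDHA, which it shares with oxidative phosphorylation, was its only member past the threshold adjusted over the list alone (adjusted p = 0.0488 in limma). SDHA was lower on 4 of 4 arrays, but adjusted over the oxidative phosphorylation list alone its adjusted p in limma was 0.224.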

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

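The tests of brightness and of haze were chosen before their results were seen, and so was the count of lists over other sign patterns; the other tests of this part were chosen after. Of 100 sets of 4 array values examined, 5 had 1 array far from the remaining 3, and chance alone flags about 1 in 20. On array 3 the X-linked list median was -0.21 against 0.20 to 0.22 on the others, and BEX2 was at -0.10 against 0.43 to 0.53. On array 4 MCM3 was at -0.028 against -0.46 to -0.40, and 818 spots were marked as ignored by the scanner software against 10 to 64. On array 1 the histone modification median was 0.068 against -0.053 to -0.046.

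Lower respiratory chain and ribosomal protein genes with 12-month semen were the widest shifts of a list. A brightness-dependent bias left by the normalisation is argued against as the whole cause. The respiratory chain median lay at percentile 0 and the ribosomal median at percentile 0.16 of 10000 random lists of equally bright genes. Part of the ribosomal pattern was shared by those random lists. Their middle median was -0.038 against -0.12, and their middle SD of array medians 0.13 against 0.20. For the respiratory chain these were -0.018 against -0.15 and 0.055 against 0.20. The random genes were drawn singly, so the percentiles speak only to brightness. Differences between embryo pools other than the bulls' age stay open. The SD of the array medians lay at percentile 100 of the random lists for the respiratory chain and 98.8 for ribosomal proteins. The genes of these 2 lists therefore move together from array to array. A dye effect shared by the genes of a list would widen this SD too, so it cannot tell pools from dye. Both calls end in camera with an estimated correlation (adjusted p = 0.865). At the preset correlation in camera, median centring in place of loess gave 1.07e-12 and 2.75e-12. Median centring leaves brightness-dependent bias in place, and both lists are bright (median log2 intensity 12.7 and 14.2). Those 2 values therefore do not add to the calls. In simulated lists with no age effect and a shared SD of 0.2, the preset correlation gave an unadjusted p under 0.05 in camera in 12 of 20. An estimated correlation did so in 1 of 20. The power of the estimated correlation to find a real shift was not simulated, so the lost calls cannot decide. The bulls' age also stays open, as an untested biological explanation.

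XIST and the X-linked list were higher on arrays 1, 2 and 4. More female embryos in the 12-month pools cannot be told apart from other causes, since XIST was higher and the median of the Y-linked genes lower on 2 of 4 arrays and the Y-linked genes lay close to background. Other differences between pools stay open too, as the SD of the array medians of the X-linked list lay at percentile 99.97 of random lists. A dye effect shared by the list's genes would widen this SD too. The age of the bulls stays an untested explanation.

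In the loess ratios, the age ratios of array 4 opposed those of the other arrays. The deposited ratios over all probes differed. As scanned, array 3 correlated there at 0.14 with array 1 and 0.17 with array 2, and array 4 at 0.21 and 0.10. By age, both arrays with exchanged dyes thus opposed arrays 1 and 2 in the deposited ratios. Haze is argued against, since without 337 hazy probes on array 4 its correlation with array 1 was -0.24. A dye bias shared by all arrays stays open: as scanned, array 4 correlated at 0.24 with array 1 and 0.11 with array 2, but at -0.15 with array 3, where the deposited ratios gave 0.016, and 3318 probes had an unadjusted dye p under 0.05 against 1799 for age. Dyes recorded the wrong way round on array 4 stay open too. Turned round, that array correlated in the loess ratios at 0.11 with array 2, 0.15 with array 3 and 0.24 with array 1. All were above 0 but below the 0.33 of arrays 1 and 2. In the deposited ratios its correlation with array 3 was 0.016 before turning, so turned round it lay below 0. Differences between the pools were not tested for this pattern.

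The 4 arrays allow 7 sign patterns that can be fitted beside the dye term, too few splits for a share under 0.05. In 7 of the 7 splits 0 probes passed, as in the real one and in the highest other. At an unadjusted p under 0.05 the real pattern gave 1799 probes and the highest other 2827, with array 4 turned round, and 3 of the 7 splits gave as many as the real one. The real pattern called 4 lists and the highest other 8, and 5 of the 7 splits called as many as the real one. Both of these counts of splits include the real one. With array 4 turned round, array 3 stands alone on its side, so that fit is not comparable with the balanced real pattern. The other balanced patterns gave 1679 probes and 8 lists with arrays 2 and 4 turned round, and 838 probes and 1 list with arrays 2 and 3.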

How the results depend on the processing

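Of 19 alternatives, 17 were fixed before the data were examined; mean pixel brightness and leaving out hazy spots were chosen after. Probes called stayed at 0 except with an array left out, where they ranged from 0 to 26 (26 without array 3, 17 without array 4). Such a fit has a lone array in 1 dye orientation, assumed to vary like the others, and in these 2 the spread came from arrays 1 and 2 alone. Unadjusted counts ranged from 961 to 9101. Median centring in place of loess gave 9101, 199 higher and 8902 lower against 933 and 866, with the median of all probes at -0.14. It leaves brightness-dependent bias in place. The median of the bright reference genes was then -0.52 and that of the dim sperm transcripts 0.0049. The bright RPS3A went from -0.35 to -0.82, and the dim MX2 stayed at 0.28. Whether brightness accounts for all of this shift was not tested. Lists called numbered 7 after median centring, 3 to 7 with an array left out, and 0 with an estimated correlation or fry; the latter count the genes' shared movement as error. Fry tests a list against no change and not against other genes. The power of camera with an estimated correlation to find a real shift was not simulated, so a call lost there cannot decide. In these 2 tests, the medians of oxidative phosphorylation (-0.15), ribosomal proteins (-0.12), the cell cycle (-0.11) and the X-linked list (0.11) are by construction as reported and lost their call. With an array left out the medians ranged from -0.24 to -0.069, from -0.21 to -0.037, from -0.14 to -0.11 and from -0.013 to 0.18. The X-linked median also turned after median centring, to -0.26 (adjusted p = 0.809), or -0.048 relative to all genes; the cause was not tested. Over all 19 alternatives the calls stood in 17 for oxidative phosphorylation, 17 for the cell cycle, 16 for ribosomal proteins and 14 for the X-linked list. Among these, the normalisation between arrays changed only brightness and not the log2 ratios, so its results were fixed in advance. Array weights were equal within each dye orientation (0.816 on arrays 1 and 2, 1.23 on arrays 3 and 4) and could not move a median. Of 398 values for the 21 other lists, 388 stayed on their side of the threshold and 10 passed it in the same test direction: glycolysis, mitochondrial biogenesis, reference genes and sperm transcripts after median centring, cholesterol biosynthesis, cumulus, trophectoderm and unfolded protein lists without array 3, the antioxidant list without array 4, and trophectoderm with mean pixel brightness. The glycolysis median turned, from 0.010 to -0.42. Of 1179 values for 70 named genes, 1173 stayed uncalled and 6 passed, 5 of them without array 3. The sign of 62 of the 70 genes held in all alternatives. ZAP70, BEX2, HSD17B7, ESRRA, APAF1 and IFNT fell below 0 after median centring, and DDX3Y and SRY turned without array 1. After median centring each of the former stayed above the median of all genes (-0.21), with ESRRA lowest at -0.20. Only ESRRA lay below the median of all probes (-0.14). Signal over background was low for SRY, above background in 5 of 8 channel signals, and for SETD7, in 3 of 4 signals at 12 months and 1 of 4 at 16; MX2 was above it in 2 of 4 at 16 months.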

Other observations

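The values of this part were singled out after the data were examined, and no explanation was tested for them. On 8 of the 25 lists array 3 alone had a median below 0. Cholesterol biosynthesis had array medians of 0.23, 0.44, -0.45 and 0.16 on arrays 1 to 4, and trophectoderm markers 0.050, 0.25, -0.19 and 0.17. The X-linked, unfolded protein, fatty acid, cavitation, cumulus and sperm lists had the same sequence of signs. Single genes had it in 7 of 19 cholesterol genes and 6 of 21 trophectoderm markers, against 8.41% of all genes. Among trophectoderm markers CYP11A1 and PAG12 had it, whereas CDX2, a transcription factor of the outer layer, stood at -0.20, 0.093, -0.0059 and 0.16. KRT8, a keratin of that layer, stood at 1.40, 0.96, -1.27 and -1.31. Its sign followed the dye and not the age, since Cy5 exceeded Cy3 on each of arrays 1 to 4. STAR, at -0.033, -0.36, -0.45 and -0.32, did not follow the steroid genes CYP11A1 and HSD3B1. The SD of the array medians exceeded the range that holds 95% of random lists of equally bright genes in 9 of the 25 lists.

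Without array 3, the only array below 0 in these lists, array 4 stands alone in its dye orientation and is assumed to vary like the others, so the spread comes from arrays 1 and 2 alone. In that fit the named genes past the adjusted threshold in limma were HSD3B1 at 1.03, CYP11A1 at 0.88, HSPA1A at 0.88, TPI1 at 0.85 and ID3 at -0.95. In camera at the preset correlation 4 further lists then passed: trophectoderm at 0.11, cholesterol at 0.20, cumulus and granulosa markers at 0.086 and the unfolded protein list at 0.095. With all 4 arrays and an estimated correlation, adjusted p was 0.865 for the first 3 of these and 0.879 for the unfolded protein list. LAMA1 passed at -0.84 without array 4, the only array where it was above 0 (0.15), again with the spread from arrays 1 and 2 alone.

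The probe with the smallest p carries no gene symbol. EMBV3_35805 stood at 0.76 ± 0.078 (SD, n = 4), between 0.69 and 0.87 on the 4 arrays, at an adjusted p of 0.821 in limma. EMBV3_39195, also unnamed, stood at 0.61 ± 0.12. Of the 20 probes with the smallest p, 11 carry no symbol.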
